A study of Mus musculus with 5 samples.

How the data were processed

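The data are 5 droplet libraries of mouse tissue, 1 per group: gene expression and TCR sequences for each of 2 treatments, and BCR sequences for the anti-CTLA-4 treatment. Per the labels' protocols, tissue was dissociated with a mouse tumour dissociation kit and loaded for a target of 5000 cells with the 5' immune profiling kit, version 1.1. Groups were taken from the sample titles. Genome builds mm10 and GRCm38 and Cell Ranger 5.0.0 are named in the submitters' processing notes. The annotation release and the V(D)J reference are not given in the sources used here. The expression files hold raw UMI counts per gene and barcode, not normalized, as deposited, with 32285 genes. The receptor files hold deposited UMI counts per assembled contig with the authors' clonotype, V, J and constant genes, and every contig in them is marked as productive, full length and from a called cell. Genes that share a symbol were summed, which left 32245 symbols.

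Before the data were examined, the filters, markers, 25 gene lists, rule for named genes and alternative settings were fixed. Barcodes with at least 200 detected genes and at most 15% mitochondrial UMIs were kept. Doublets were called per library with Scrublet in scanpy 1.11.5. It marked 52 control cells (0.949%), which were removed. It marked only 3 anti-CTLA-4 cells (0.0735%), so the 137 cells with the highest scores, the expected rate of 3.35%, were removed instead. The doublet rule thus differed between the libraries. Both libraries were clustered together without batch correction on log counts per 10000, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2). TCR and immunoglobulin segments, mitochondrial and ribosomal protein genes were left out of the variable genes. T and NK cells, and B-lineage cells, were clustered again by the same steps.

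Clusters were called by a class name followed by "-like" only from markers fixed in advance. The thresholds of the naming rule were set after the data were seen. A cluster needed at least 3 markers detected in 20% of its cells and a mean log2 fold of at least 1.0 over the other cells, with a constant of 20 added to each scaled level. A T subcluster was CD8 or CD4 where its ratio of Cd8a plus Cd8b1 to Cd4 was above 8.0 or under 0.5, and otherwise stayed unnamed. Clusters with few markers, low depth or leading genes of another class stayed unnamed. Unnamed clusters with Ptprc in under 5% of cells form the Ptprc-negative group. That class names are rebuilt from markers means that shares can differ from any the authors gave.

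Shares have exact Clopper-Pearson 95% intervals. Within classes of at least 100 cells in each library, UMIs were summed per class and divided by the class total, and ratios of anti-CTLA-4 over control have exact conditional binomial intervals (scipy 1.17.1). Free RNA, doublets and differences between animals are not in these intervals. A count of 0 was bounded with 3 counts, a fixed floor that lies below the exact upper 95% bound. Named genes have at least 50 UMIs over both libraries, a UMI in 10% of the class's cells where they are higher, and there at least 20% of the gene's highest class level. Named are the 5 highest and the 5 lowest ratios per class, ordered by the interval bound nearest to 1, and from each list the 2 members farthest from 1 by that bound and the 2 with the most UMIs, of which the text prints some. Mitochondrial, ribosomal, haemoglobin, receptor segment, Xist, Y-linked and unnamed-model genes were excluded. The B-cell genes, Foxp3, Ctla4 and similar genes of the study's topic were fixed in advance as always reportable. Il13, Il5, Il17a, Crabp1, Krt20 and the Cdkn2 genes were picked after their values were seen.

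For each list the median log2 ratio of members with at least 20 UMIs was computed, with 0.5 UMI added to each sum, and its percentile among 10000 random lists of the same size matched on expression in 20 bins. The comparison was tested on simulated counts with counting error only, so coverage near the intended level was set in advance. UMIs that cluster in few cells and differences between animals were not simulated. Over 8676 genes of the T-like class, intervals covered the true ratio for 96.2% of genes, and excluded 1 for 76.8% of genes set to a ratio of 2 and 96.7% of those set to 4. Shares of cells with a UMI were computed after thinning each cell to 1000 UMIs. TCR clonality used the deposited clonotypes, with 1000 draws of the larger library to the smaller one's cell number. Gene coordinates are from GENCODE M21 on GRCm38 and are 1-based.

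Free RNA was gauged from 171 genes that lead the Ptprc-negative clusters and took 8.16% of that group's UMIs. In T-like cells they stood at 9.49% of that level in the control and at 1.51% in the anti-CTLA-4 library. Settings fixed in advance as alternatives were a mitochondrial limit of 10%, at least 500 genes, doublets kept, resolutions 0.5 and 2.0, cells thinned to 2000 UMIs, immune cells as the base of shares, other scalings of ratios, lists of members with at least 100 UMIs, other definitions of CD4 T cells and clonotypes, and subsets of the receptor barcodes. Added after the data were seen were clustering without free-RNA genes, subtraction of free RNA from the control and single clusters in place of classes. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.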

Results

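BALB/c mice carried subcutaneous tumours of CT26, a mouse colon carcinoma line, and received either an antibody against CTLA-4 (clone 9H10, 100 µg into the peritoneum on days 5, 8 and 11) or phosphate-buffered saline. CTLA-4 is an inhibitory receptor of T cells that competes with CD28 for its ligands. Tissue was collected on day 13, dissociated with a kit for tumours and run as droplet libraries of the 5' immune profiling type, version 1.1. The labels call the material only tissue. There were 5 libraries: gene expression and T cell receptor (TCR) sequences for each treatment, and B cell receptor (BCR) sequences for the anti-CTLA-4 treatment. A control BCR library was not analysed here. With 1 library per group no difference has a replicate check, no test across samples was made, and all intervals are 95% intervals that cover counting error only.

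The control expression library held 5649 barcodes and 86478313 unique molecular identifiers (UMIs), with a median of 6827 UMIs per barcode. The anti-CTLA-4 library held 4186 barcodes and 19989467 UMIs, with a median of 3147.5 per barcode. After filtering, 5430 and 3946 cells remained. The TCR libraries gave 282 and 1529 cells with a productive beta chain, and the BCR library gave 472 cells with a productive heavy chain.

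The main comparison asks which cells made up the tissue with and without CTLA-4 blockade, the study's title being about follicular T and B cell contact and antibody production. T-like cells were 54.0% of the anti-CTLA-4 library (2129 cells, interval 52.4 to 55.5) and 7.0% of the control (380 cells, 6.33 to 7.71), a ratio of 7.71 (6.91 to 8.62). B-like cells were 15.7% (620 cells) against 1.34% (73 cells), a ratio of 11.7 (9.16 to 15.1). Plasma-like cells were 2.36% of the anti-CTLA-4 library (93 cells) and 0 of 5430 in the control. A floor of 3 counts gives 0.0552% there, and the exact upper bound is 0.0679%. Against that floor their share was 42.7-fold higher, with an exact lower bound of 34.0 for the ratio. Monocyte/macrophage-like cells were lower, at 7.53% against 16% (ratio 0.471, 0.412 to 0.538), and NK-like cells were 2.64% against 4.42% (ratio 0.596, 0.469 to 0.754). A group of unnamed cells without Ptprc, the gene of the pan-leukocyte marker CD45, made up 48.4% of the control (2627 cells) and 0.583% of the anti-CTLA-4 library (23 cells), 83.0-fold higher in the control (55.2 to 131).

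**Figure D1:**
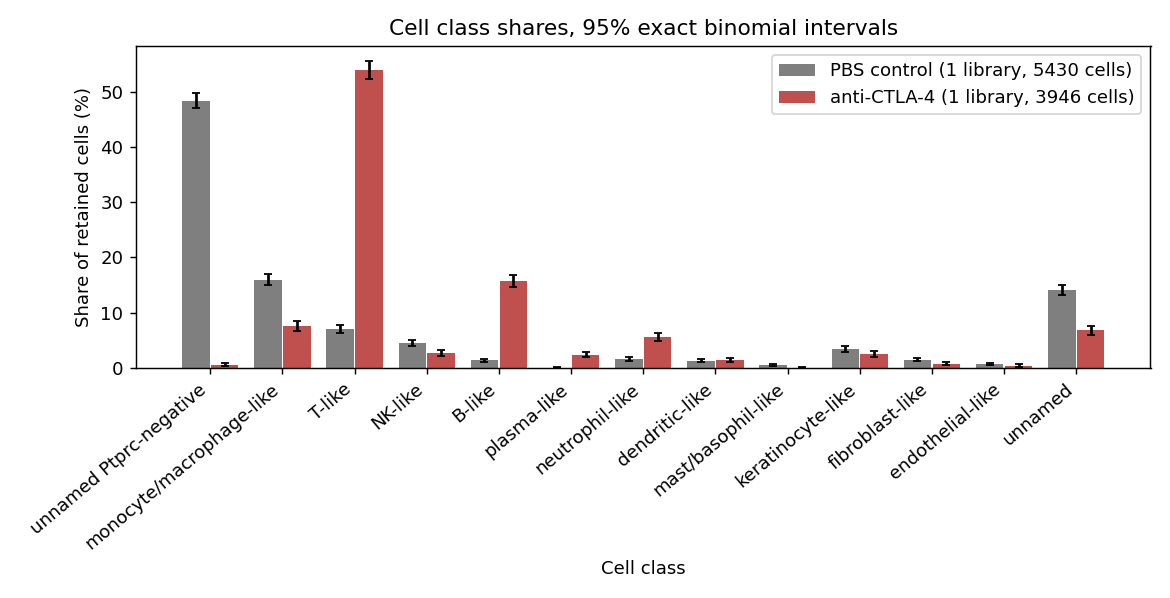
Share of retained cells (percent, y axis) in each cell class (x axis) of the control library (grey, 5430 cells) and the anti-CTLA-4 library (red, 3946 cells). Bars are shares of 1 library each with 95% exact binomial intervals, and T-like cells stand at 7.0% and 54.0%.

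Among the smaller classes, neutrophil-like cells were 5.52% of the anti-CTLA-4 library against 1.53% of the control (ratio 3.61, 2.79 to 4.71; 6.31 with at least 500 genes per cell). Dendritic-like cells had a ratio of 1.06 (0.725 to 1.53) over all cells. Mast/basophil-like cells were 27 in the control and 0 of 3946 in the anti-CTLA-4 library, where a floor of 3 counts gives 0.0760% (exact upper bound 0.0934%). Keratinocyte-like cells were 3.39% and 2.46%, fibroblast-like cells 1.49% and 0.710%, and endothelial-like cells 0.681% and 0.405% of control and anti-CTLA-4 cells. The clusters left without a name by thresholds set after the data were seen, other than the Ptprc-negative group, held 14.0% of the control and 6.79% of the anti-CTLA-4 library.

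Because the Ptprc-negative group filled so much of the control, shares were also taken over immune cells alone (1739 control and 3514 anti-CTLA-4 cells). T-like cells were then 60.6% against 21.9% (ratio 2.77) and B-like cells 17.6% against 4.20% (ratio 4.20). Monocyte/macrophage-like cells were 8.45% against 49.9% (ratio 0.170) and NK-like cells 2.96% against 13.8% (ratio 0.214). On this base neutrophil-like cells had a ratio of 1.30 (1.01 to 1.69), and dendritic-like cells were lower, at 1.51% against 3.97% (0.38, 0.261 to 0.552). Plasma-like cells were 15.3-fold higher against a floor of 3 counts (exact lower bound 12.2).

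The T and NK cells were clustered again, and the named T subsets differed between the libraries. CD4 T-like cells were 38.9% of 2138 anti-CTLA-4 T cells and 3.90% of 410 control T cells, and CD8 T-like cells were 25.7% and 6.83%. Treg-like cells, the regulatory subset marked by Foxp3, were 6.64% (142 cells) against 22.2% (91 cells), a ratio of 0.299 (0.228 to 0.394). The direction depends on the base. Over all cells, where the Ptprc-negative group fills much of the control, the Treg-like ratio was 2.15 (1.64 to 2.83; 1.42 without free-RNA genes), and over immune cells, a base added after the data were seen, it was 0.772 (0.589 to 1.02; 0.511 without free-RNA genes). Gamma-delta T-like cells were 1.54% (33 cells) against 1.95% (8 cells). Unnamed T subclusters held 65.1% of the control T cells and 27.3% of the anti-CTLA-4 T cells. When the genes that lead the Ptprc-negative clusters were left out of this clustering, a choice made after the data were seen, the CD4 T-like share of the control was 26.7% and the CD8 T-like share 14.7%, and the Treg-like share was 22.1% against 4.35%.

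Foxp3, the Treg transcription factor (X:7573644-7595245 in GRCm38), was measured in cells thinned to 1000 UMIs to remove the depth gap. In CD4 T-like cells, Treg included, a Foxp3 UMI was found in 35.5% of 93 control cells (25.8 to 46.1) and in 4.21% of 949 anti-CTLA-4 cells (3.03 to 5.70), after 14 and 24 shallower cells were left out. The control value rests on 91 Treg-like and only 16 other CD4 T-like cells, since most control T cells stayed unnamed. It was 19.1% with CD4 T cells picked by Cd4 and Cd8 UMIs and 18.3% with free-RNA genes left out of the clustering, against 3.27% and 4.84% in the anti-CTLA-4 library. The unthinned shares were 54.2% of 107 cells and 8.94% of 973 cells. Monocyte/macrophage-like cells, which should lack Foxp3, gave 0 of 849 thinned control cells (allowing up to 0.353%) and 0.347% of 288 anti-CTLA-4 cells. Their median depths were 4216 and 6553 UMIs against 2204 and 3081 in the CD4 T-like cells. Ctla4 itself (1:60887000-60915832) had a UMI in 52.7% and 16.1% of the thinned control and anti-CTLA-4 CD4 T-like cells (65.4% and 29.7% unthinned), and Icos, a costimulatory receptor, in 69.9% and 30.3% (84.1% and 48.7% unthinned). Picked by Cd4 and Cd8 UMIs, the control shares were smaller, at 30.9% against 17.2% for Ctla4 and 45.6% against 33.6% for Icos. The matching shares in thinned monocyte/macrophage-like cells were 0.236% and 0.694% for Ctla4 and 0.353% and 1.04% for Icos. With 91 of 107 control and 142 of 973 anti-CTLA-4 cells Treg-like, the CD4 T-like shares compare mostly Treg-like with mostly other cells. Cluster 11 held 148 of 150 control and 404 of 417 anti-CTLA-4 Foxp3 UMIs of T-like cells. In it Foxp3 had a ratio of 0.853 (0.705 to 1.04) and Ctla4 of 0.728 (0.639 to 0.831). Unthinned, Ctla4 was found in 52.4% and 72.9% of its cells.

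Follicular helper T cells help B cells in germinal centres, and 3 of their genes, Bcl6, Cxcr5 and Il21, were detected in few CD4 T-like cells of either library. Bcl6, their master transcription factor, had a UMI in 4.30% of the thinned control CD4 T-like cells (1.18 to 10.6) and in 3.79% of the anti-CTLA-4 ones (2.67 to 5.21). Which library was higher depends on the cells taken, since with CD4 T cells picked by Cd4 and Cd8 UMIs the shares were 0% of 68 cells and 4.13% of 581. The unthinned shares were 7.48% and 11.0%, against 4.15% and 4.38% in monocyte/macrophage-like cells. The thinned control share is 4 cells, all Treg-like, and over the whole T-like class Bcl6 was higher with anti-CTLA-4, at 242 UMIs against 11 (ratio 2.39, 1.31 to 4.86). Cxcr5, the receptor for follicle homing, was found in 0 of 93 thinned control cells, which allows up to 3.23%, and in 0.421% of the anti-CTLA-4 cells (unthinned 2.80% and 1.23%, with 0 in the monocyte/macrophage-like cells). Unthinned, Cxcr5 was detected in 12 of the 142 anti-CTLA-4 cells of the subcluster named Treg-like (8.45%, 4.44 to 14.3) and in 0 of the 831 other CD4 T-like cells. After thinning these were 2.94% of 136 cells and 0 of 813, which allows up to 0.369%. Pdcd1, an inhibitory receptor, was found in 15.1% and 8.85% (26.2% and 17.8% unthinned), and in 0 of the thinned monocyte/macrophage-like cells of either library. Il21, the helper cytokine, gave 0 UMIs in the control cells and 3 in the anti-CTLA-4 cells, too few to compare. In the clustering used for these values no T subcluster met the marker rule for a follicular helper name, but under 2 other settings 1 did. With a mitochondrial limit of 10% it held 2 control and 48 anti-CTLA-4 cells, and with cells thinned to 2000 UMIs before clustering 0 and 31. Of these 50 and 31 cells, 45 and 28 lay in the subcluster named Treg-like, while 3 and 0 held a Foxp3 UMI and 9 and 6 a Cxcr5 UMI. The Treg-like name of the anti-CTLA-4 library thus covers some cells with a follicular helper profile, and the Cxcr5 above is not assigned to Treg cells. With at least 500 genes, doublets kept, resolution 0.5 or 2.0, or without free-RNA genes, no subcluster met the rule.

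Within the T-like class, regulatory and exhaustion genes stood lower in the anti-CTLA-4 library, and the Th1 list and 3 of 10 naive and central memory genes stood higher. Cluster 11 held 147 of the 380 control cells and cluster 0 held 137, while in the anti-CTLA-4 library cluster 0 held 857, cluster 5 held 410, cluster 10 held 380, cluster 15 held 261 and cluster 11 held 221. Of the regulatory T list, 13 of 14 measured members were at least 1.5-fold lower, with a median log2 ratio of -1.18, the 0th percentile of 10000 matched random lists. Il10, an anti-inflammatory cytokine, had a ratio of 0.117 (0.0511 to 0.271) and Tnfrsf9, an activation-induced costimulatory receptor, 0.338 (0.316 to 0.362). In the exhaustion list 8 of 11 members were lower, with a median of -0.82 and the 0th percentile. Ctla4, Tigit, Entpd1 and Tnfrsf9 are on both the regulatory and the exhaustion list, so these are not separate results. The Th1 list had a median of 0.53 (percentile 99.99), with 6 of 12 members higher and 0 lower, among them Tnf, an inflammatory cytokine (ratio 3.52), and Il12rb2, a subunit of the interleukin-12 receptor (ratio 2.49).

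For the naive and central memory T list the median was 0.37 (percentile 99.9), with Lef1, a transcription factor of naive T cells, at 1.93 (1.63 to 2.31) and Satb1, a chromatin organiser, at 1.89. Ccr7, the receptor for lymph node homing, went the other way at 0.698 (0.656 to 0.744). The follicular helper T list had a median of -0.28 (percentile 7.02), with 3 members higher and 5 lower of 15. Its cytokine Il4, which type 2 helper cells also make, gave 240 UMIs in 0.517% of the anti-CTLA-4 cells and 0 in the control. Against a floor of 3 counts this was 8.71-fold higher (exact lower bound 7.03, with UMIs of the same cell not independent). At that share few of the 380 control cells would hold a UMI, so no difference in the share of cells is shown. The cytotoxicity list went both ways in the class. There Gzma, granzyme A, had a ratio of 7.48 (5.50 to 10.4) and Gzmb, granzyme B, of 0.342 (0.317 to 0.369). In cluster 11 alone 8 of 8 measured members of that list were lower (median -1.98), and in cluster 0 the median of 3 members was -1.37. Lists of genes that T cells hardly express also stood lower, such as matrix and TGF-beta response (-1.90, 0th percentile), and free RNA in the control adds to such values. With free RNA subtracted from the control, a step chosen after the data were seen, that list was at -0.88. The hypoxia and glycolysis list was at -0.63 (0th percentile), with 10 of 15 members lower. The dissociation and heat stress list stood lower too, at -0.38 (percentile 0.170), with -0.87 in cluster 0 and -1.04 in cluster 11, so handling is not separated from these differences. These class values mix subsets. In cluster 0 alone the exhaustion list had a median of 0.34, and in cluster 11 alone the regulatory list had -0.56 and the Th1 list -0.44, the Th1 and exhaustion lists thus changing sign.

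The genes farthest from a ratio of 1 in T-like cells by the counting bound were, on the higher side, Serpinb1a, a serine protease inhibitor (13:32842092-32851185; ratio 6.16, 4.05 to 9.86), Nrap (4.32), Cxcr6, a chemokine receptor of tissue-resident T cells (9:123806475-123811760; 3.01, 2.62 to 3.48), Pou6f1 (4.81) and Rnaset2b (3.72). On the lower side were Lag3, an inhibitory receptor (6:124904361-124911705; 0.180, 0.155 to 0.210), Areg, an epidermal growth factor receptor ligand (0.178), Ier3 (0.183), Csrp2 (0.166) and Cst3, a cysteine protease inhibitor (0.226). In cluster 11 alone Cxcr6 had a log2 ratio of -2.45. Areg and Csrp2 are among the 171 genes that lead the Ptprc-negative clusters. Subtracting free RNA from the control, a step chosen after the data were seen, left Areg (log2 -2.49 to -2.35) and Csrp2 (-2.60 to -2.15) inside their counting intervals and moved Ier3 from -2.45 to -2.05. Crabp1, the retinoic acid binding protein that marks that group, had a UMI in 50.3% of control and 0.329% of anti-CTLA-4 T-like cells.

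NK-like cells (cluster 12) had lower levels of Gzmb and Gzma, which encode granzymes, in the anti-CTLA-4 library (104 cells) than in the control (240 cells). The class sat in different subclusters: subcluster 7 held 180 control and 11 anti-CTLA-4 cells and subcluster 9 held 30 and 84, so the values below mix a difference in subclusters with differences inside them. Gzmb had a ratio of 0.166 (14:56258838-56262260; 0.142 to 0.193) and Gzma, which is also a marker used to name the class, of 0.318 (0.299 to 0.338). Zbtb32, a transcription factor of proliferating NK cells, was at 1 UMI against 49 (ratio 0.0468, 0.00116 to 0.273), Capg, an actin capping protein, had a ratio of 0.197 and Lag3 0.127. Higher were Cxcr6 (7.34, 4.82 to 11.5), the anti-apoptotic Bcl2a1b (7.59) and Bcl2a1d (5.29), the marrow-retention receptor Cxcr4 (5.37) and the activation-induced nuclear receptor Nr4a3 (5.17). The cytotoxicity list had a median log2 ratio of -0.31 (percentile 3.20), although Ccl5, a chemokine on that list, was at 2.84. The type I interferon response list had a median of -1.17 (0th percentile), the proliferation list -1.13 (0th percentile; only -0.29 for members with at least 100 UMIs) and the naive and central memory T list 1.02 (percentile 99.99). The dissociation and heat stress list also stood higher, at 0.44 (percentile 99.2, 7 members higher and 1 lower), so handling is not separated from genes induced by activation such as Nr4a3. Its median was 0.22 with at least 500 genes and 0.29 with doublets kept. The free-RNA genes stood at 8.99% of their level in the Ptprc-negative group in control NK-like cells and at 1.91% in anti-CTLA-4 ones.

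Monocyte/macrophage-like cells of the anti-CTLA-4 library had lower medians of the type I interferon, Fc receptor and complement, and proliferation lists. Their median of the hypoxia and glycolysis list was higher. Different clusters held the class. Cluster 1 held 656 of the 867 control cells and 58 of the 297 anti-CTLA-4 cells, and cluster 6 held 211 and 239. Of the type I interferon response list 13 of 15 members were lower and 0 higher (median log2 ratio -1.60, 0th percentile), with Isg15, an interferon-induced ubiquitin-like protein, at 0.239 (0.219 to 0.260). In cluster 6 alone this list had a median of -1.11, again at the 0th percentile. The dissociation and heat stress list was at 0.31 in cluster 6 (percentile 99.5) and at -0.23 in the class (percentile 18.4), so handling is not separated. The interferon-gamma response list went both ways, with 8 of 20 members lower and 5 higher (median -0.52, percentile 0.0700; -0.29 in cluster 6 alone), the lower ones including the T cell attracting chemokines Cxcl9 at 0.296 and Cxcl10 at 0.263. The Fc receptors and complement list had -0.72 (0th percentile; -0.45 in cluster 6 alone), with C1qa at 0.349, and the proliferation list -2.64 (0th percentile; -0.47 in cluster 6 alone). The hypoxia and glycolysis list had a median of 0.37 (percentile 98.95; 0.19 in cluster 6 alone and 0.21 with doublets kept), with 8 of 17 members higher and 2 lower. The angiogenic factor Vegfa was at 3.42 (3.08 to 3.79) and the oxygen sensor Egln3 at 4.05, while the glycolytic enzyme Aldoa was at 0.861. Lymphocyte lists differed in this class as well, with naive and central memory T at 1.03 (percentile 99.99), exhaustion at 1.28 (percentile 100) and cytotoxicity at -1.87 (0th percentile). The naive and central memory T list was at 0.46 in cluster 6 alone and turned to -0.23 for members with at least 100 UMIs. RNA of lymphocytes in these cells was not separated.

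Named by the counting bound in this class were Cd200, an immune inhibitory ligand (16:45382135-45409053; ratio 29.9, 15.3 to 66.8), Nos2, inducible nitric oxide synthase (11:78920787-78960254; 15, 10.6 to 21.6), Fam20c, a secretory pathway kinase (17.3), Fbxo32, a ubiquitin ligase subunit (13.3), and Sdc1, a heparan sulfate proteoglycan (7.65). The lowest were Ccl12, a monocyte attracting chemokine (11:82101845-82103400; 0.0450, 0.0344 to 0.0579), the Fc receptor-like Fcrls (0.0662), the cell cycle genes Pclaf (0.0657) and Birc5 (0.0778), and Tmem171 (0.0775). These ratios reflect in part which clusters held the class. In cluster 6 alone the log2 ratios were 3.13 for Cd200 (4.83 in the class), 2.20 for Nos2 (3.89), 1.52 for Sdc1 (2.93), 2.95 for Fbxo32 (3.71) and -2.70 for Ccl12 (-4.46). Nos2 is on the inflammatory macrophage list, of which 1 of 11 members was higher and 5 lower in the class. Its median was -0.56 (percentile 0.685), and -0.90 in cluster 6 alone. The alternatively activated macrophage list was at -0.56 too (percentile 0.52), with 3 of 12 members higher and 6 lower. With doublets kept, Fam20c was at 3.12 (4.07 in the class; 3.28 with at least 500 genes), Pclaf at -1.92 (-3.86) and Birc5 at -1.46 (-3.62). Cxcl13, the chemokine that draws B cells into follicles (5:95956951-95961068), gave 62 UMIs against 4, a ratio of 31.4 (11.6 to 119), in 2.36% and 0.115% of the cells, the latter being 1 cell. In cluster 6 alone the ratio was 7.84 (2.89 to 29.8), and in the unnamed cluster 7 Cxcl13 was lower, at 0.194 (0.0473 to 0.603). UMIs of the same cell are not independent, so these Cxcl13 intervals are too narrow. Over all retained cells Cxcl13 gave 127 of 85139551 UMIs in the control and 83 of 19183854 in the anti-CTLA-4 library. Its share of all UMIs was thus higher with anti-CTLA-4, although it rests on few cells. These were 13 control cells (0.239%) and 16 anti-CTLA-4 cells (0.405%). Most of the control Cxcl13 UMIs lay outside the monocyte/macrophage-like class. The free-RNA genes stood at 16.4% of their level in the Ptprc-negative group in the control and at 13.4% in the anti-CTLA-4 library. For 82 of these genes, chosen for low levels in anti-CTLA-4 immune cells, the values were 7.74% and 0.538%. That choice makes the second value low in advance. The 16.4% and 13.4% thus do not show that free RNA was equal in both libraries.

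**Figure D2:**
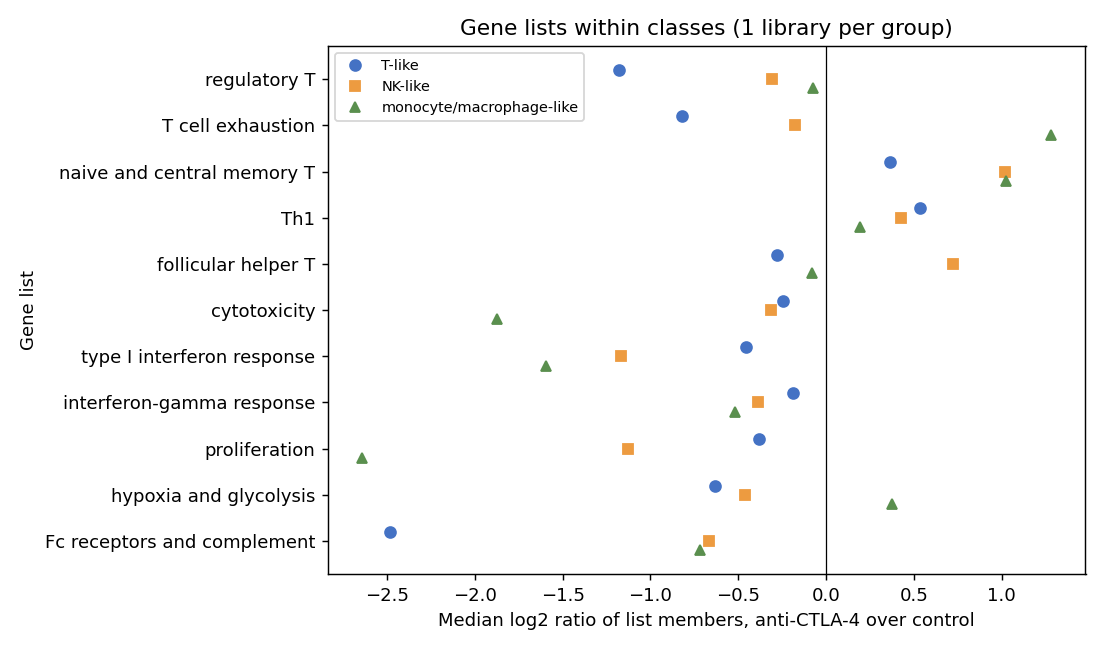
Median log2 ratio of list members, anti-CTLA-4 over control (x axis), for 11 gene lists (y axis) within T-like cells (circles), NK-like cells (squares) and monocyte/macrophage-like cells (triangles), 1 library per group. The regulatory T list stands at -1.18 in T-like cells and the type I interferon response list at -1.60 in monocyte/macrophage-like cells.

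TCR sequences ask whether T cells of the same clone recurred. Cells in clonotypes of 2 or more cells were 28.8% of 1529 cells in the anti-CTLA-4 library (26.5 to 31.1) and 4.96% of 282 cells in the control (2.74 to 8.19). The largest clonotype held 25 cells, 23 of them CD8 T-like, against 2 cells in the control. When the anti-CTLA-4 library was drawn down to 282 cells 1000 times, the mean share was 15.5% and the central 95% of draws ran from 10.3 to 20.6, above the control value. The draws match cell number but not subsets. Of the 282 control cells 26 were named CD8 T-like, and of the 1529 anti-CTLA-4 cells 427 were. Expanded cells were 46.1% of 427 CD8 T-like cells (41.3 to 51.0), 28.5% of 568 CD4 T-like cells (24.8 to 32.4) and 11.4% of 105 Treg-like cells (6.05 to 19.1) in the anti-CTLA-4 library. In the control they were 6 of 26 (8.97 to 43.6), 2 of 14 (1.78 to 42.8) and 3 of 64 (0.977 to 13.1). For each of these subsets the intervals of the libraries overlap. Of the unnamed T cells 13.0% of 353 (9.70 to 17.0) were expanded with anti-CTLA-4, and 3 of 148 (0.420 to 5.81) in the control. These shares by subset are not matched for cell number. The libraries shared 8 beta chain CDR3 amino acid sequences of 278 and 1203, and 2 of these at the nucleotide level.

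**Figure D3:**
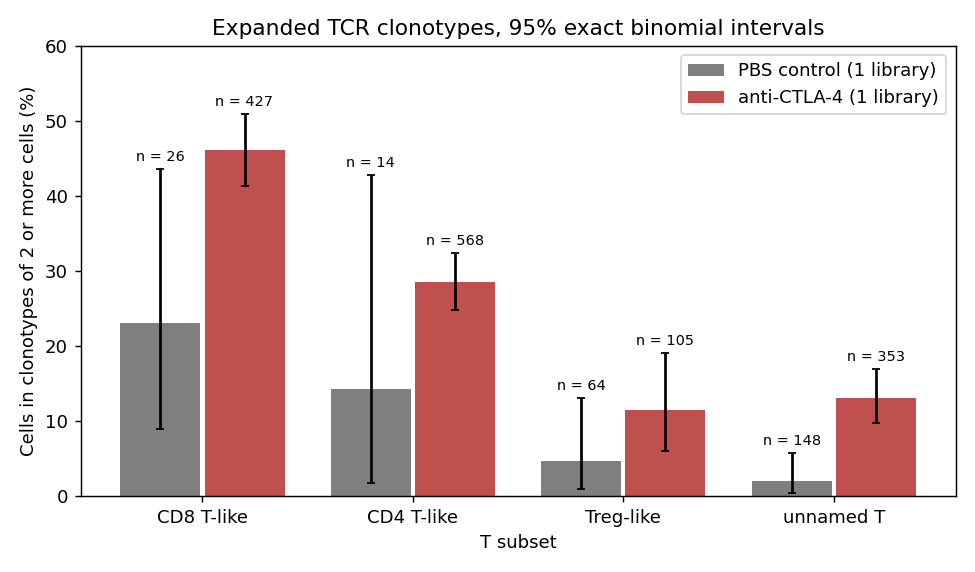
Percent of cells with a beta chain in clonotypes of 2 or more cells (y axis) per T subset (x axis) in the control (grey) and anti-CTLA-4 (red) libraries, 1 library each, with 95% exact binomial intervals and the number of cells above each bar. In the anti-CTLA-4 library the share is 46.1% in CD8 T-like and 11.4% in Treg-like cells.

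In the B lineage of the anti-CTLA-4 library, antibody class followed the cell's cluster. Ighd is among the markers that name B-like cells, and Ighg1, Ighg2b and Ighg2c are among the leading genes of the plasma-like subcluster. Cluster and antibody class may thus not be independent. Of the plasma-like subcluster 65 of 67 cells with a heavy chain were class-switched (97.0%, 89.6 to 99.6), 56 of them IgG1. B-lineage subcluster 7 had 20 of 20 switched. Its marker name was B-like, but all 20 of its cells belong to the plasma-like class of the first clustering. In the germinal centre B-like subcluster 9 of 15 were switched (60%, 32.3 to 83.7). The remaining B-like subclusters, 0 to 3, had between 0 and 2 switched cells of 41 to 100 each, the rest being IgM, IgD or not given. Germinal centre B-like cells were 26 of 713 B-lineage cells in the anti-CTLA-4 library (3.65%) and 2 of 73 in the control (2.74%), a ratio of 1.33 (0.333 to 11.6) on a control base that includes 61 cells of a shallow unnamed subcluster. Over all cells the ratio was 17.9 (4.48 to 156), and over immune cells 6.43 (1.61 to 55.9), each resting on the 2 control cells. Clonotypes of the plasma-like subcluster were many, 55 among 67 cells.

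Over all 472 heavy-chain cells, IgM was 47.5% (42.9 to 52.1), IgG1 32.4% (28.2 to 36.8), IgD 12.9%, IgG2b 1.48% and IgG3 0.636%. A further 1.27% carried the name of the Ighg2c gene, a name that the reference gives and that may stand for IgG2a in BALB/c mice. Among barcodes of B-lineage clusters alone, IgG1 was 21.7% and IgM 55.6%, since 61 of the IgG1 cells were retained cells outside the B lineage and 10 were barcodes that had been filtered out. Kappa light chains were found in 98.3% of 658 cells (97.0 to 99.2). In the expression libraries Ighg1 gave 59424 UMIs with anti-CTLA-4 and 3 in the control, and Jchain, the joining chain of secreted antibodies, 56415 and 9.

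**Figure D4:**
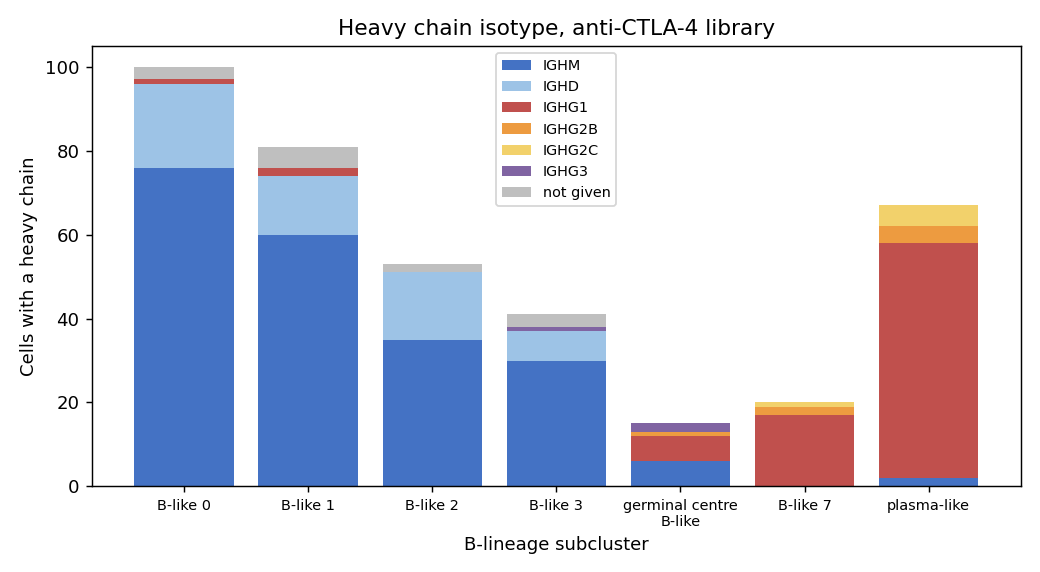
Number of cells with a heavy chain (y axis) by isotype (colours) in each B-lineage subcluster (x axis) of the anti-CTLA-4 library. IgG1 accounts for 56 of the 67 plasma-like cells and IgM for 76 of the 100 cells of B-like subcluster 0.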

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

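All tests in this part were chosen after the results were seen, except the test of the cell filters in the last paragraph.

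The BCR library, which has no control here, showed a signal outside the B lineage. A single IgG1 pair, heavy chain IGHV2-2 with IGHJ3 and light chain IGKV4-68, was assembled in 65 barcodes, and 59 retained cells outside the B lineage carried it, 46 of them T-like. An expanded B-lineage clone is argued against by the TCR library: 34 of these 59 cells (57.6%, 44.1 to 70.4) also held a TCR beta chain, against 0 of 620 B-like cells (upper bound 0.593%) and 1 of 93 plasma-like cells. Since 46 of the 59 were T-like by expression, and 1456 of all 2129 T-like cells held a beta chain, this largely follows from their class. Free RNA spread evenly over droplets is argued against too: 54 cells outside the B lineage held 3 or more Ighv2-2 UMIs (12:113588267-113588702) where an even spread of the 418 UMIs gives 1.06, with a mean of 5.12 UMIs in the 59 cells and 0.0365 in the others. A candidate explanation is that pieces of an antibody-secreting cell, itself not captured, were carried with other cells: Jchain, Mzb1 and Xbp1 stood above other T-like cells by 1.08 times (0.848 to 1.34) what plasma-like cells carry per heavy chain V gene UMI. The heavy chain of this pair reached at most 14 UMIs per barcode, against a median of 2943 in plasma-like cells.

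T-like and B-like cells made up more of the anti-CTLA-4 library. Shares that sum to 100% with fewer Ptprc-negative cells cannot be the whole cause, since the B-like share of immune cells still had a ratio of 4.20 (3.29 to 5.43). Blood carried into the sample cannot be told apart from other sources, because haemoglobin in T-like and B-like cells rested on 2 control and 4 anti-CTLA-4 UMIs (ratio 0.199, 0.0286 to 2.20). Lymph node tissue carried into the sample also cannot be told apart, since only 1 cell in each library held UMIs of 2 or more high endothelial venule genes, with 16 endothelial-like cells in the anti-CTLA-4 library. The treatment stays open as an untested explanation, as 1 library per group confounds it with the animal and the dissociation.

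The Ptprc-negative group of the control may be CT26 tumour cells. This line is known to lack the Cdkn2a and Cdkn2b locus, and the group held 0 UMIs of both genes (4:89274471-89294653 and 4:89306299-89311039) among 73658488, where the fibroblast-like level would give 836; only 13 UMIs set that level. A median fibroblast gene stood at 1.67% of its level in fibroblast-like cells, though Pdgfra stood at 29.5%. The group was formed from clusters that no marker list named, the fibroblast list included, so low values were partly set in advance. The genes that lead the group took 11.3% of UMIs in control fibroblast-like cells against 8.16% in the group. Fibroblasts missed by the markers are thus not excluded. The cell filters applied here did not remove such cells from the deposited anti-CTLA-4 barcodes, as 0 of 240 removed barcodes (0%, upper bound 1.53%) held 10 or more Crabp1 UMIs. Cell calling before deposit was not examined. Treatment, tumour size and sampling of the tissue stay open, untested, for the difference between libraries.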

How the results depend on the processing

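No paired analysis was possible because each group has 1 library and the results come from no test. Single clusters, subset shares of immune cells, free RNA subtraction and clustering without free-RNA genes were chosen after the results were seen. Of 139 planned recomputations of main values, 111 stayed within the counting interval, 28 moved beyond it and 0 changed direction, though shares per library are counted singly and cannot change direction. Of the recomputations of main values added later, 14 stayed, 9 moved and 2 changed direction. Main values were picked by hand: class and Treg-like shares, Foxp3 and Bcl6 shares, most receptor shares and some gene lists. For all other values 503 planned recomputations stayed, 51 moved and 3 changed direction. Of those added later for these other values, 114 stayed, 59 moved and 13 changed direction. Unless a cause is named, the cause was not tested.

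With immune cells as the base, the share ratios moved by construction: T-like 2.77, B-like 4.20, NK-like 0.214, monocyte/macrophage-like 0.170 and neutrophil-like 1.30. At resolution 0.5 they were 6.07 for T-like, 0.542 for monocyte/macrophage-like and 0.172 for Treg-like cells, and at 2.0 the Treg-like ratio was 0.215. It was 0.197 without free-RNA genes. The values at 0.5 cover other cells. A cluster of 185 control and 1268 anti-CTLA-4 cells led by Lef1 and Satb1 was left unnamed there, leaving 195 and 860 T-like cells. It had 6 T cell markers detected and stayed unnamed by the rule on leading genes of another class. The monocyte/macrophage-like class grew to 1137 and 448 cells. Keeping doublets gave 0.543 for monocyte/macrophage-like cells, at least 500 genes gave 6.31 for neutrophil-like cells, and thinning to 2000 UMIs gave 0.0188 for the Ptprc-negative group. With doublets kept the monocyte/macrophage-like class grew from 867 control and 297 anti-CTLA-4 cells to 1169 and 473. A shallow cluster of 448 and 198 cells led by Acp5 and Ctsk was part of it. Values of this class under that setting thus do not isolate doublets.

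Among lists in T-like cells, requiring 500 genes turned type I interferon from -0.46 to 0.29, members with 100 UMIs turned inflammatory macrophage to 0.95, and subtracting free RNA turned alternatively activated macrophage to 2.89 and neutrophil chemokines to 1.12. In cluster 0 alone the medians were 0.34 for exhaustion, 0.26 for B cell identity, 0.25 for costimulation, 0.52 for interferon-gamma, 0.78 for type I interferon, 0.30 for MHC class I, 0.0669 for MHC class II and 1.09 for neutrophil chemokines, all with changed sign. Regulatory T was -0.65, naive T 0.56 and Th1 0.31 there. In cluster 11 alone Th1 was -0.44 and proliferation 0.28, both with changed sign, as was Cxcr6 at -2.45; regulatory T was -0.56 and exhaustion -0.62. In monocyte/macrophage-like cells the naive T list turned to -0.23 with members of 100 UMIs, and type I interferon was -1.36; proliferation was -1.34 with doublets kept. In cluster 6 alone dissociation stress turned to 0.31 and neutrophil chemokines to -0.50, type I interferon was -1.11 and proliferation -0.47. In NK-like cells proliferation was -0.29 with members of 100 UMIs.

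Bcl6 in CD4 T-like cells was 0% of control cells against 4.13% when these were picked by Cd4 and Cd8 UMIs, which turns the order of the libraries, and 7.29% of anti-CTLA-4 cells thinned to 2000 UMIs. Foxp3 in control cells was 55.4% thinned to 2000 UMIs, 19.1% picked by Cd4 and Cd8 UMIs and 18.3% without free-RNA genes; in anti-CTLA-4 cells it was 5.72% with doublets kept and 7.17% thinned to 2000 UMIs. Thinning to 2000 UMIs keeps more UMIs per cell and also leaves out more shallow cells. Expanded CD8 T-like cells were 51.2% among barcodes with alpha and beta chains. With B-lineage barcodes only, IgG1 was 21.7%, IgM 55.6%, switched cells 25.9% and cells in clonotypes of 2 or more 12.4%, which removes the widespread pair by construction. With at least 5 heavy chain UMIs, IgG1 was 45.1%, switched cells 50.7% and such clonotypes 29.1%. The 380 control T-like cells, with a median of 1950.5 UMIs, limit the precision of comparisons within T cells.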

Other observations

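The tests of explanations are in the part on results flagged for a closer look; the genes below were picked after their values were seen.

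The cytokine genes Il13 and Il5 gave many UMIs in few T-like cells of the anti-CTLA-4 library. Il13, a type 2 cytokine (11:53631324-53634702), gave 921 UMIs in 0.939% of the anti-CTLA-4 T-like cells and 1 UMI in the control, a ratio of 100 (17.9 to 3963). Il5, which drives eosinophils, gave 258 UMIs in 0.658% of cells and 0 in the control, at least 9.36-fold higher (exact lower bound 7.56). Il17a, which recruits neutrophils, had 285 UMIs in 0.517% of cells against 8 UMIs in 1 control cell, a ratio of 3.88 that rests on that cell. Csf2, a growth factor of myeloid cells, had a ratio of 6.13 (3.75 to 10.8). UMIs from the same cell are not independent, so these intervals are too narrow. At such shares few of the 380 control T-like cells would hold a UMI, so for Il13, Il5 and Il17a no difference in the share of cells is shown.

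Nrap, named in T-like cells, was higher in every class compared: its ratio was 4.32 in T-like, 5.32 in NK-like and 3.91 in monocyte/macrophage-like cells. It encodes a muscle anchoring protein and no cause of the difference between libraries was tested. In the Ptprc-negative group of the control, Krt20, an intestinal keratin (11:99428403-99438150), had a UMI in 79.7% of cells, while Epcam, an epithelial adhesion gene, had one in 0.952%.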
